A study of Homo sapiens with 54 samples.

How the data were processed

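The series holds 54 samples of cells derived from H1 by the labels: 32 bulk RNA libraries, 3 single-cell RNA libraries, 8 libraries of chromatin accessibility and 11 of chromatin immunoprecipitation. The chromatin libraries were not analysed here, because the questions taken up concern RNA. Bulk RNA was prepared with TRIzol, polyA selection and SMART-seq2 per the labels. The bulk table holds TPM of 58735 genes in 32 libraries, made by the authors with build hg38 and deposited as 1 combined file. The labels name Trim Galore 0.4.4, HISAT2, HTSeq 0.11.1 and DESeq2 among the tools for the whole series, and which of them made the TPM is not given in the sources used here. The single-cell files hold counts of unique molecular identifiers (UMIs) for 36601 genes, made by the authors with Cell Ranger, version 7.1.0 for days 7 and 9 and 7.0.0 for day 12 per the file headers, on GRCh38 per the labels.

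Library columns were matched to samples by title, with 0 columns left over. Groups were read from the labels alone: 11 bulk groups and 3 single-cell days. TPM were used as deposited and transformed to log2 of TPM plus a pseudocount of 1. Genes needed a mean of at least 1 TPM over the libraries of a fit, which left 13131 genes for 3D against 2D at day 12 (a fit of 8 libraries) and 13384 for all 3D groups (a fit of 28). Of the genes in the bulk table, 36226 were matched to a reference gene list by Ensembl identifier or, failing that, by symbol. Because 1546 identifiers repeat a symbol already held by another, single-gene values are given per identifier. Of 10 housekeeping genes checked, 0 values in the table were 0.

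Group differences were tested gene by gene with limma 3.58.1 in R 4.3.3, whose moderated test shares the spread of all groups in a fit, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 13 results are 3D against 2D at day 12, days 16, 19 and 23 against day 12, FBS against no FBS on average and at each day, the interaction of FBS with day, SP6A and SP14 against day 12 and against each other, and E. coli against the mean of 3D days 12, 16, 19 and 23 without FBS. Of 45 fixed lists of genes (29 of pathways, 16 of cell types), those with at least 5 measured members were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, and with fry. The lists were written before the files were opened. A list is described by its camera result, by calls over all genes and by calls adjusted over the list alone.

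Genes were named by a rule written before the files were opened. It takes up to 8 largest increases and 8 largest decreases per comparison (5 each for SP6A, SP14 and FBS at single days) among called genes with at least 5 TPM in the higher group whose libraries all lie on 1 side. It adds up to 4 members with the lowest adjusted p of each described list and a fixed set of genes, with MYC, KLF2, KLF4, MAF, MKI67, TOP2A, CD14, CD68, CD163, MRC1, CSF1R, SPI1, S100A8 and S100A9 among them. The text gives a selection of these.

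Single-cell counts were filtered at 1000 UMIs, 500 genes and at most 15% mitochondrial counts, which kept 6767, 11727 and 7961 of 7034, 12891 and 8159 barcodes at days 7, 9 and 12. Scrublet, run in scanpy on each library with an expected doublet rate of 0.06, removed 216, 435 and 369 cells. Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 gave 21 clusters of 25435 cells (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). Clusters of at least 50 cells took a name where at least 5 markers, and most markers detected, of 1 cell type reached 20 CPM and 2 times the level in the other cells, and no other type had more markers among the 10 genes most raised. Clusters of low depth with no such marker among the 10 stayed unnamed. This rule was chosen after the clusters were seen. It named 11 clusters in 9 classes. Cell cycle phase was called from 42 S and 52 G2/M genes after thinning each cell to 3000 UMIs. With 1 library per day, shares carry exact binomial intervals at 95% that hold counting error only. Genes are compared between days by pooled counts, at 50 CPM or more in the higher day, with 10 genes listed per direction and a floor of 3 counts where a day had fewer.

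Read totals of the bulk libraries are not given in the sources used here. Replicates of a group correlated at 0.891 to 0.968 on the log2 scale, and the E. coli libraries at 0.657. No 2 libraries of a group were identical. The fit was tested on simulated data built from the gene means and spread of all libraries in a fit, with equal noise per library. For comparisons among 3D groups these were all 28 libraries, so the lower agreement of the E. coli libraries is not kept. The fit recovered 37% of genes changed by 1 on the log2 scale and 74% of those changed by 2 for 3D against 2D. The figures were 26 and 71% for day 16 against day 12, 50 and 98% for FBS on average, 6 and 42% for SP14 against SP6A, and 26 and 73% for E. coli. The share of false calls there was 1.77, 4.9, 3.27, 2.04 and 7.48%. The clustering was tested on simulated data of 1800 cells in 6 types of equal size, each with its own raised genes, and returned the types. That simulation held no doublets, rare types or differences between days, so it does not show how stable the real clusters are. The total of UMIs was 171021284, 169396511 and 156301231 at days 7, 9 and 12.

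Alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, median-ratio scaling, a trend with robust moderation, array weights, a replicate block, leaving out each library, fits on the compared groups alone, and other controls for E. coli. For single cells they were resolution 1.0, doublets kept, no thinning, and a stricter filter of 3000 UMIs, 1500 genes and 10% mitochondrial counts. Fits without the E. coli libraries, without 3 clone-named genes, and on genes above 0 in both E. coli libraries were added once the values had been seen.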

Results

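Macrophages were differentiated from the human pluripotent stem cell line H1 on a porous 3D microscaffold, and the series asks how that niche shapes their programme, their division and their yield beside flat 2D culture. Bulk RNA was measured in 32 libraries of 11 groups: 2D day 12 and 3D day 12 (4 libraries each), 3D days 16, 19 and 23 without and with FBS in the label (3 each), and 3D groups labelled SP6A, SP14 and E. coli (2 each). Droplet single-cell RNA was measured in 1 library at each of days 7, 9 and 12 of 3D culture. Read totals of the bulk libraries are not given in the sources used here, so their depth is described by the genes detected. On average 12838 genes reached 1 TPM in 2D day 12 and 12100 in 3D day 12. The other 3D groups lay between 11893 and 13140, except for the E. coli group with 8028. The single-cell libraries kept 6551, 11292 and 7592 cells at days 7, 9 and 12, with a median of 24179, 13032 and 16617 UMIs per cell. Every bulk change is a difference of mean log2(TPM + 1), and "rose" and "fell" are used for genes that passed the adjusted test. The p-values measure only the spread between samples, which the labels do not describe as separate cultures. Where a camera call on a list of genes is lost once the correlation between genes is estimated from the data, that adjusted p is printed beside it. Every other list call below holds under that estimate. The 3 genes known only by the names of genomic clones (FP236383.2, FP236383.3 and FP671120.3) shared a single value in each of the 32 libraries. Together they took 0.418 ± 0.0669% of the TPM (SD, n = 4) in 2D day 12, 7.69 ± 2.10% (SD, n = 4) in 3D day 12 and 28.4 ± 4.09% (SD, n = 3) in 3D day 19 with FBS. This leaves less of the TPM for all other genes.

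The comparison of 3D with 2D at day 12 asks what growth in the porous niche changes in macrophages of the same age. Of 13131 genes tested, 1710 rose and 3249 fell in 3D. Scaling each library by the median ratio of its genes changed that split to 2376 up and 2553 down. It moved the median change of all genes from -0.212 to -0.045, so the balance of up and down calls depends on the scaling. The largest increases were in secreted signals of inflammation. IL6 (ENSG00000136244, chromosome 7, 22727200 to 22731998), a cytokine of the acute phase response, rose from 2.83 ± 2.58 to 163 ± 37.96 TPM (SD, n = 4 each, log2 change 5.67, adjusted p = 0.000167). CXCL8, an attractant of neutrophils, rose from 15.5 ± 4.17 to 307 ± 59.5 TPM (SD, n = 4 each, log2 change 4.24, adjusted p = 3.02e-05). IL1B, the inflammasome-processed cytokine, rose from 58.4 ± 5.55 to 1107 ± 77.2 TPM (SD, n = 4 each, log2 change 4.22, adjusted p = 6.5e-06). CXCL2, another neutrophil attractant, rose from 2.22 ± 0.986 to 119 ± 11.2 TPM (SD, n = 4 each, log2 change 5.28, adjusted p = 2.25e-05). CCL3, a chemokine of activated macrophages, rose from 146 ± 14.5 to 2136 ± 151 TPM (SD, n = 4 each, log2 change 3.86, adjusted p = 9.11e-06). CCL4 rose from 86.6 ± 22.6 to 1765 ± 161 TPM (SD, n = 4 each, log2 change 4.37, adjusted p = 2.31e-05). The near-identical copies CCL4L2 and CCL3L1 (log2 change 5.55 and 4.41) cannot be told apart from CCL4 and CCL3 with certainty. Among 35 inflammatory cytokines and NF-kB targets tested, 27 rose, 3 fell and 5 were not called (27 up and 3 down adjusted over the list alone, camera adjusted p = 1.58e-14). Immediate early genes, which respond within minutes to stimulation, changed as well. Of 20 tested, 10 rose, 4 fell and 6 were not called (10 up and 4 down adjusted over the list alone, camera adjusted p = 0.00122, adjusted p = 0.16 with an estimated correlation). NR4A2, an orphan nuclear receptor, rose (log2 change 4.28, adjusted p = 1.15e-05). DUSP1, a phosphatase that restrains MAP kinases, rose (log2 change 4.13, adjusted p = 2.25e-05). The AP-1 subunit JUND fell (log2 change -3.51, adjusted p = 9.09e-05). The 3D libraries thus held more RNA for signals that call neutrophils and monocytes, and whether by other shares of cells or by change within macrophages was not tested.

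**Figure D1:**
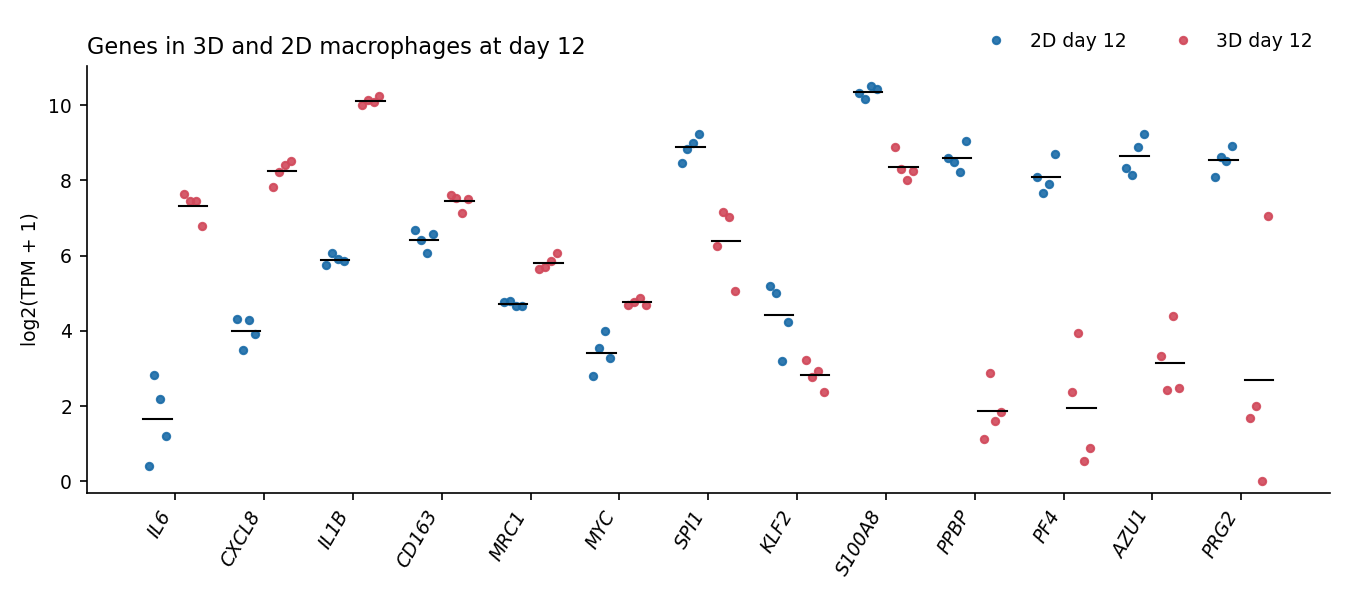
Values of 13 genes in the 4 libraries of 2D day 12 and the 4 libraries of 3D day 12 on a log2(TPM + 1) axis, where each point is a library and each line the mean of a group. IL6, CXCL8 and IL1B lie higher in every 3D library, whereas PPBP, PF4 and AZU1 lie lower, and PRG2 stays high in 1 of the 4 3D libraries.

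The largest decreases in 3D were in markers of other blood lineages. PPBP (ENSG00000163736, chromosome 4, 73986439 to 73988190), a platelet chemokine precursor, fell from 393 ± 96.1 to 3.03 ± 2.30 TPM (SD, n = 4 each, log2 change -6.73, adjusted p = 2.67e-05). Its neighbour in platelet granules, PF4, fell from 283 ± 93.7 to 4.99 ± 6.53 TPM (SD, n = 4 each, log2 change -6.16, adjusted p = 0.000498). ITGA2B, the platelet fibrinogen receptor subunit, fell from 35.5 ± 12.7 to 0.648 ± 0.453 TPM (SD, n = 4 each, log2 change -4.44, adjusted p = 9.82e-05). All 10 megakaryocyte markers tested fell (camera adjusted p = 1.01e-05, adjusted p = 0.0615 with an estimated correlation, 10 down adjusted over the list alone). AZU1, a protein of neutrophil granules, fell from 417 ± 145 to 9.46 ± 7.23 TPM (SD, n = 4 each, log2 change -5.49, adjusted p = 0.000143). MPO, the myeloperoxidase of the same granules, fell from 175 ± 52.4 to 19.2 ± 8.27 TPM (SD, n = 4 each, log2 change -3.17, adjusted p = 0.000445). Of 11 granulocyte or neutrophil markers tested, 0 rose, 10 fell and 1 was not called (0 up and 11 down adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.0586 with an estimated correlation). PRG2, an eosinophil granule protein, fell from 377 ± 85.4 TPM (SD, n = 4) in 2D to 2.21, 2.99, 0 and 132 TPM in the 3D libraries (log2 change -5.85, adjusted p = 0.0084). GATA1, a transcription factor of the erythroid, megakaryocyte and mast cell lineages, fell from 20.8 ± 6.89 to 0.850 ± 1.08 TPM (SD, n = 4 each, log2 change -3.69, adjusted p = 0.000508). Of 6 mast cell, basophil or eosinophil markers 1 rose, 3 fell and 2 were not called (1 up and 4 down adjusted over the list alone, camera adjusted p = 0.279). HBD, a minor adult globin, fell too (log2 change -5.35, adjusted p = 0.00296). HBA2, an alpha globin copy nearly identical to HBA1, fell as well (log2 change -5.08, adjusted p = 0.016). Of 12 erythroid markers 0 rose, 3 fell and 9 were not called (0 up and 3 down adjusted over the list alone, camera adjusted p = 0.639). The 3D libraries thus held less RNA of these platelet and neutrophil genes than the 2D libraries.

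Among macrophage genes the change was mixed. The scavenger receptor CD163 (ENSG00000177575, chromosome 12, 7470811 to 7503777), which takes up haemoglobin, rose from 85.96 ± 15.2 to 174 ± 23.3 TPM (SD, n = 4 each, log2 change 1.02, adjusted p = 0.00429). MRC1, the mannose receptor, rose from 25.3 ± 1.24 to 55.5 ± 7.41 TPM (SD, n = 4 each, log2 change 1.10, adjusted p = 0.00125). C1QB, a complement subunit made by resident macrophages, rose from 231 ± 32.1 to 890.2 ± 95.1 TPM (SD, n = 4 each, log2 change 1.95, adjusted p = 0.00018). TIMD4, a receptor for apoptotic cells, rose from 6.43 ± 2.25 to 53.9 ± 17.98 TPM (SD, n = 4 each, log2 change 2.88, adjusted p = 0.000403). The lipid carrier APOE fell from 287 ± 55.3 to 38.03 ± 12.9 TPM (SD, n = 4 each, log2 change -2.92, adjusted p = 0.000175). Of 19 tissue-resident and yolk-sac-type macrophage genes, 10 rose, 2 fell and 7 were not called (11 up and 2 down adjusted over the list alone, camera adjusted p = 0.000454, adjusted p = 0.0899 with an estimated correlation). MAF, a transcription factor of mature macrophages, fell (log2 change -0.75, adjusted p = 0.00855). SPI1, the lineage-determining factor PU.1, fell from 479 ± 103 to 94.8 ± 50.8 TPM (SD, n = 4 each, log2 change -2.51, adjusted p = 0.00321). CSF1R and CD68 were not called (log2 change -0.28, adjusted p = 0.178 and log2 change -0.28, adjusted p = 0.187). The lipopolysaccharide co-receptor CD14 rose from 516 ± 64.1 to 954 ± 109 TPM (SD, n = 4 each, log2 change 0.89, adjusted p = 0.00411). Monocyte genes went down. S100A8, an alarmin of monocytes and neutrophils, fell from 1317 ± 134 to 336 ± 96.3 TPM (SD, n = 4 each, log2 change -2.002, adjusted p = 0.000433). Its partner S100A9 fell too (log2 change -0.61, adjusted p = 0.0279). The call of S100A9 is lost when 1 of the libraries is left out, under median-ratio scaling and with the replicate block. Of 14 monocyte genes tested 1 rose, 11 fell and 2 were not called (1 up and 11 down adjusted over the list alone, camera adjusted p = 0.000802, adjusted p = 0.0619 with an estimated correlation). The lysosomal protease CTSD fell (log2 change -2.03, adjusted p = 0.000426). LAMP1, a protein of the lysosomal membrane, fell (log2 change -1.65, adjusted p = 0.000174). Of 32 lysosome genes 8 rose, 12 fell and 12 were not called (9 up and 13 down adjusted over the list alone, camera adjusted p = 0.802). The antigen-presenting HLA-DRA also fell (log2 change -1.56, adjusted p = 0.00419). Of 10 HLA class II genes, 5 fell and none rose (camera adjusted p = 0.073, 6 down adjusted over the list alone).

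The series is concerned with macrophage proliferation and self-renewal, and the genes of division did not move together. MYC (ENSG00000136997, chromosome 8, 127735434 to 127742951), which drives growth and self-renewal, rose from 10.1 ± 3.81 to 25.98 ± 1.77 TPM (SD, n = 4 each, log2 change 1.35, adjusted p = 0.00404). KLF2, a zinc finger factor linked to quiescence and to self-renewal of macrophages, fell from 23.2 ± 12.5 to 6.28 ± 1.76 TPM (SD, n = 4 each, log2 change -1.58, adjusted p = 0.0197). That call is lost without the last 3D replicate. Its relative KLF4 was not called (log2 change 0.29, adjusted p = 0.427). ID2, an inhibitor of differentiation factors, rose from 174 ± 43.96 to 469.5 ± 57.2 TPM (SD, n = 4 each, log2 change 1.46, adjusted p = 0.00147). CCND2, a D-type cyclin that starts the cycle, fell (log2 change -1.60, adjusted p = 0.00162). Of 13 self-renewal regulators, 2 rose, 3 fell and 8 were not called (2 up and 3 down adjusted over the list alone, camera adjusted p = 0.422). RRM2, the ribonucleotide reductase subunit of S phase, rose from 20.8 ± 4.10 to 123 ± 57.9 TPM (SD, n = 4 each, log2 change 2.38, adjusted p = 0.0018). SLBP, which binds histone mRNA, rose (log2 change 1.74, adjusted p = 0.000519). The chromatin remodeller HELLS fell (log2 change -1.38, adjusted p = 0.00228). Of 42 S phase genes, 18 rose, 1 fell and 23 were not called (18 up and 1 down adjusted over the list alone, camera adjusted p = 7.69e-05, adjusted p = 0.185 with an estimated correlation). The proliferation marker MKI67 fell (log2 change -0.67, adjusted p = 0.0213). Its call is lost when 1 of the libraries is left out, under median-ratio scaling and with the replicate block. The topoisomerase TOP2A, which untangles chromosomes, fell (log2 change -1.58, adjusted p = 0.00437). CKS2, a partner of cyclin-dependent kinases, rose (log2 change 1.43, adjusted p = 0.00149). Of 52 G2/M genes 6 rose, 10 fell and 36 were not called (6 up and 9 down adjusted over the list alone, camera adjusted p = 0.256). RNA levels of such genes leave open whether more or fewer cells divided. Of 30 ribosome biogenesis genes, 10 rose, 7 fell and 13 were not called (11 up and 7 down adjusted over the list alone, camera adjusted p = 0.074). ODC1, the enzyme of polyamine synthesis, rose (log2 change 1.28, adjusted p = 0.00337). Transcripts of the mitochondrial genome took 8.02 ± 0.607% of the TPM (SD, n = 4) in 3D and 4.60 ± 0.170% (SD, n = 4) in 2D. Of 13 mitochondrially encoded genes, 9 rose, 1 fell and 3 were not called (9 up and 1 down adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.0899 with an estimated correlation). MT-CO1, a subunit of cytochrome oxidase, rose (log2 change 1.24, adjusted p = 0.00058).

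The later 3D libraries address how the RNA of the 3D libraries changes as the culture goes on from day 12. At day 16, 1382 of 13384 genes rose and 837 fell. At day 19, 853 rose and 722 fell, and at day 23 1400 rose and 2027 fell. Array weights gave 4444 calls at day 16 and 4016 at day 19, and the fit without the E. coli libraries 3435 and 2567. Under the median-ratio scaling the numbers became 765 up and 1422 down at day 16 and 672 up and 1109 down at day 19. The median change moved from 0.177 to -0.08 and from 0.039 to -0.091. The 3 comparisons share the 4 day 12 libraries, so a value peculiar to those libraries would enter all of them.

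Genes of resident macrophages rose at days 16 and 19. SELENOP (ENSG00000250722, chromosome 5, 42799880 to 42811892), a selenium carrier secreted by resident macrophages, rose from 6.56 ± 2.26 to 194 ± 37.8 TPM (SD, n = 4 and 3, log2 change 4.72, adjusted p = 7.78e-10) at day 16. At day 19 it was up from 6.56 ± 2.26 to 205 ± 109 TPM (SD, n = 4 and 3, log2 change 4.69, adjusted p = 1.09e-09). The transglutaminase F13A1, a marker of alternatively activated macrophages, rose from 13.3 ± 3.55 to 283 ± 31.7 TPM (SD, n = 4 and 3, log2 change 4.34, adjusted p = 3.42e-11) at day 16. RNASE1, a secreted ribonuclease, rose from 427 ± 111 to 1713 ± 63.0 TPM (SD, n = 4 and 3, log2 change 2.04, adjusted p = 2.31e-07). TIMD4 fell from 53.9 ± 17.98 to 2.50 ± 1.17 TPM (SD, n = 4 and 3, log2 change -3.96, adjusted p = 6.11e-07). Of 20 genes of the tissue-resident list at day 16, 15 rose, 1 fell and 4 were not called (18 up and 1 down adjusted over the list alone, camera adjusted p = 1.87e-13). At day 19, 12 rose, 1 fell and 7 were not called (12 up and 1 down adjusted over the list alone, camera adjusted p = 1.49e-11). At day 23, 6 rose, 7 fell and 7 were not called (6 up and 9 down adjusted over the list alone, camera adjusted p = 0.548). TIMD4 went from 33.4, 52.2, 52.7 and 77.2 TPM to listed at 0 (adjusted p = 2.35e-09) by then. MRC1 fell (log2 change -1.68, adjusted p = 5.98e-06), and so did the hyaluronan receptor LYVE1 (log2 change -2.79, adjusted p = 4.08e-07). The scavenger receptor STAB1 rose from 443 ± 186 to 2119 ± 149 TPM (SD, n = 4 and 3, log2 change 2.37, adjusted p = 2.75e-06). CD163 rose against day 12 at every later day (log2 change 1.01, adjusted p = 0.00379 at day 16, log2 change 0.84, adjusted p = 0.0183 at day 19 and log2 change 1.24, adjusted p = 0.000419 at day 23). Its call at day 19 is lost when 1 of the libraries is left out and under median-ratio scaling. So the RNA of several genes of resident macrophages went up at days 16 and 19, and that of TIMD4 went down at day 16.

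Large increases came from genes of several kinds. MARCO (ENSG00000019169, chromosome 2, 118942194 to 118994660), a bacterial scavenger receptor, rose from 39.4 ± 6.75 to 1213 ± 37.4 TPM (SD, n = 4 and 3, log2 change 4.93, adjusted p = 3.48e-10) at day 23. The monocyte attractant CCL8 rose from 1.29 ± 0.992 to 71.2 ± 18.6 TPM (SD, n = 4 and 3, log2 change 5.08, adjusted p = 9.43e-07). SERPINA1, the protease inhibitor antitrypsin, rose from 5.91 ± 1.20 to 183 ± 6.22 TPM (SD, n = 4 and 3, log2 change 4.75, adjusted p = 9.05e-08). MSR1, a receptor for modified lipoproteins, rose from 1.01 ± 0.782 to 40.01 ± 7.12 TPM (SD, n = 4 and 3, log2 change 4.42, adjusted p = 2.66e-10) at day 19. CH25H, which makes an oxysterol from cholesterol, rose from 2.52 ± 1.89 to 90.9 ± 4.23 TPM (SD, n = 4 and 3, log2 change 4.86, adjusted p = 6.49e-08) at day 16. Lysosome genes rose at all 3 days. PSAP, the precursor of saposins, rose from 465 ± 17.5 to 1387 ± 24.2 TPM (SD, n = 4 and 3, log2 change 1.58, adjusted p = 5.07e-07) at day 16. The protease LGMN, which matures other proteases, rose from 76.99 ± 3.67 to 258 ± 13.4 TPM (SD, n = 4 and 3, log2 change 1.73, adjusted p = 2.95e-06) at day 16. Of 32 lysosome genes, 17 rose, 0 fell and 15 were not called (23 up and 0 down adjusted over the list alone, camera adjusted p = 1.84e-10) at day 16. At day 19, 17 rose, 0 fell and 15 were not called (17 up and 0 down adjusted over the list alone, camera adjusted p = 1.02e-10). At day 23, 17 rose, 3 fell and 12 were not called (19 up and 4 down adjusted over the list alone, camera adjusted p = 3.49e-09).

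AURKB, a mitotic kinase, fell from 134 ± 13.7 to 6.49 ± 4.44 TPM (SD, n = 4 and 3, log2 change -4.43, adjusted p = 2.31e-07) at day 16. UBE2C, which feeds the anaphase-promoting complex, fell from 270.2 ± 40.4 to 12.99 ± 8.45 TPM (SD, n = 4 and 3, log2 change -4.42, adjusted p = 5.77e-06). MKI67 fell from 19.02 ± 3.10 to 2.69 ± 1.85 TPM (SD, n = 4 and 3, log2 change -2.55, adjusted p = 0.000117) at day 16. TOP2A fell from 66.6 ± 26.3 to 6.13 ± 3.63 TPM (SD, n = 4 and 3, log2 change -3.28, adjusted p = 0.00129) at day 16. Neither was called at day 19 (log2 change -0.32, adjusted p = 0.716 and log2 change -0.12, adjusted p = 0.96). Neither was called at day 23 (log2 change -0.69, adjusted p = 0.236 and log2 change 0.01, adjusted p = 1). Of 52 G2/M genes, 0 rose, 36 fell and 16 were not called (0 up and 42 down adjusted over the list alone, camera adjusted p = 2.38e-29) at day 16. At day 19, 1 rose, 5 fell and 46 were not called (1 up and 5 down adjusted over the list alone, camera adjusted p = 0.000313, adjusted p = 0.127 with an estimated correlation). At day 23, 0 rose, 32 fell and 20 were not called (0 up and 34 down adjusted over the list alone, camera adjusted p = 1.83e-08). Of 39 S phase genes, 0 rose, 10 fell and 29 were not called (0 up and 22 down adjusted over the list alone, camera adjusted p = 7.06e-12) at day 16. At day 19, 0 rose, 6 fell and 33 were not called (0 up and 6 down adjusted over the list alone, camera adjusted p = 1.46e-05). At day 23, 0 rose, 28 fell and 11 were not called (0 up and 32 down adjusted over the list alone, camera adjusted p = 5.32e-11). CDCA7, a chromatin factor of replicating cells, fell from 21.96 ± 7.70 to 0.470 ± 0.272 TPM (SD, n = 4 and 3, log2 change -3.91, adjusted p = 2.92e-08) at that day. MYC fell from 25.98 ± 1.77 to 6.71 ± 1.16 TPM (SD, n = 4 and 3, log2 change -1.82, adjusted p = 7e-05) at day 23. ID1, a target of BMP signalling, fell from 233 ± 27.7 to 0.557 ± 0.630 TPM (SD, n = 4 and 3, log2 change -7.30, adjusted p = 1.15e-09) at day 16. It was down at day 23 as well (log2 change -6.18, adjusted p = 1.08e-08). PLAC8, a gene of monocytes and progenitors, went from 94.7, 118, 122 and 113 TPM to listed at 0 (adjusted p = 1.18e-07) at day 16. The embryonic globin HBZ went from 1.82, 462, 909 and 57.2 TPM to listed at 0 (adjusted p = 0.00384). HBG2 and HBA1, each a near-identical copy of a neighbour, were listed at 0 as well. MPO went from 19.3, 9.87, 29.9 and 17.5 TPM to listed at 0 (adjusted p = 4.1e-10). Of 9 granulocyte markers at day 16 0 rose, 6 fell and 3 were not called (0 up and 6 down adjusted over the list alone, camera adjusted p = 1.61e-08). S100A8 fell from 336 ± 96.3 to 16.5 ± 3.60 TPM (SD, n = 4 and 3, log2 change -4.25, adjusted p = 3.27e-08) at day 16. VCAN, a monocyte proteoglycan, fell from 12.6 ± 3.61 to 0.327 ± 0.566 TPM (SD, n = 4 and 3, log2 change -3.40, adjusted p = 4.89e-09). Of 13 monocyte genes 0 rose, 7 fell and 6 were not called (0 up and 8 down adjusted over the list alone, camera adjusted p = 1.81e-10).

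Inflammatory genes receded from their day 12 level. NFKBIA, the inhibitor that NF-kB itself induces, fell from 978 ± 70.2 to 232 ± 20.4 TPM (SD, n = 4 and 3, log2 change -2.07, adjusted p = 9.92e-08) at day 19. The chemokine CCL20 fell from 69.8 ± 20.9 to 2.22 ± 0.145 TPM (SD, n = 4 and 3, log2 change -4.42, adjusted p = 1.48e-09). IL1B fell from 1107 ± 77.2 to 289.9 ± 67.6 TPM (SD, n = 4 and 3, log2 change -1.95, adjusted p = 9.47e-06). Of 37 genes of the inflammatory list, 2 rose, 13 fell and 22 were not called (7 up and 13 down adjusted over the list alone, camera adjusted p = 0.000238) at day 16. At day 19, 0 rose, 17 fell and 20 were not called (0 up and 19 down adjusted over the list alone, camera adjusted p = 1.61e-10). At day 23, 7 rose, 17 fell and 13 were not called (7 up and 17 down adjusted over the list alone, camera adjusted p = 0.0427, adjusted p = 0.283 with an estimated correlation). NR4A2 fell from 23.1 ± 3.11 to 3.41 ± 1.14 TPM (SD, n = 4 and 3, log2 change -2.48, adjusted p = 3.44e-06). The AP-1 gene FOSB fell from 22.8 ± 9.07 to 2.41 ± 1.53 TPM (SD, n = 4 and 3, log2 change -2.81, adjusted p = 6.9e-06) at day 19. Of 20 immediate early genes 1 rose, 12 fell and 7 were not called (1 up and 15 down adjusted over the list alone, camera adjusted p = 2.91e-11). Of 24 cholesterol biosynthesis genes, 0 rose, 9 fell and 15 were not called (0 up and 9 down adjusted over the list alone, camera adjusted p = 4.67e-08) at day 16. FDPS, which makes farnesyl units, fell from 653 ± 26.2 to 129 ± 13.9 TPM (SD, n = 4 and 3, log2 change -2.34, adjusted p = 9.39e-07).

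Libraries labelled FBS, set beside those of the same day without it, address what FBS changes. Averaged over days 16, 19 and 23, 2484 of 13384 genes rose and 2105 fell with FBS. By day, 1066 rose and 1351 fell at day 16, 1712 and 1636 at day 19. At day 23, 1187 rose and 651 fell (with the median-ratio scaling 868 up and 881 down, the median change moving from 0.16 to 0). The effect of FBS differed between days in 1728 genes by the interaction test of the same model. With 1 library left out the calls at day 16 went down to 1510. Array weights gave 2842 calls at day 23 and 2913 for the interaction. Genes of sterol synthesis fell at each day. SQLE, which commits squalene to sterols, fell from 43.2 ± 10.1 to 5.72 ± 1.91 TPM (SD, n = 9 each, log2 change -2.74, adjusted p = 2.62e-08) on average over the days. FDPS (ENSG00000160752, chromosome 1, 155308866 to 155320665) fell from 255 ± 103 to 66.6 ± 19.2 TPM (SD, n = 9 each, log2 change -1.85, adjusted p = 9.53e-09). Of 24 cholesterol biosynthesis genes, 0 rose, 21 fell and 3 were not called (0 up and 23 down adjusted over the list alone, camera adjusted p = 1.01e-16) on average. Singly by day, 17, 20 and 16 fell at days 16, 19 and 23. The sterol exporters ABCG1 and ABCA1 rose (log2 change 3.10, adjusted p = 9.3e-11 and log2 change 2.42, adjusted p = 4.38e-10). SCD, an enzyme that desaturates fatty acids, fell (log2 change -3.32, adjusted p = 5.31e-09). Of 22 LXR targets and lipid genes 7 rose, 8 fell and 7 were not called (7 up and 8 down adjusted over the list alone, camera adjusted p = 0.803). With FBS, the libraries held less RNA to make sterols and more of these exporters.

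**Figure D2:**
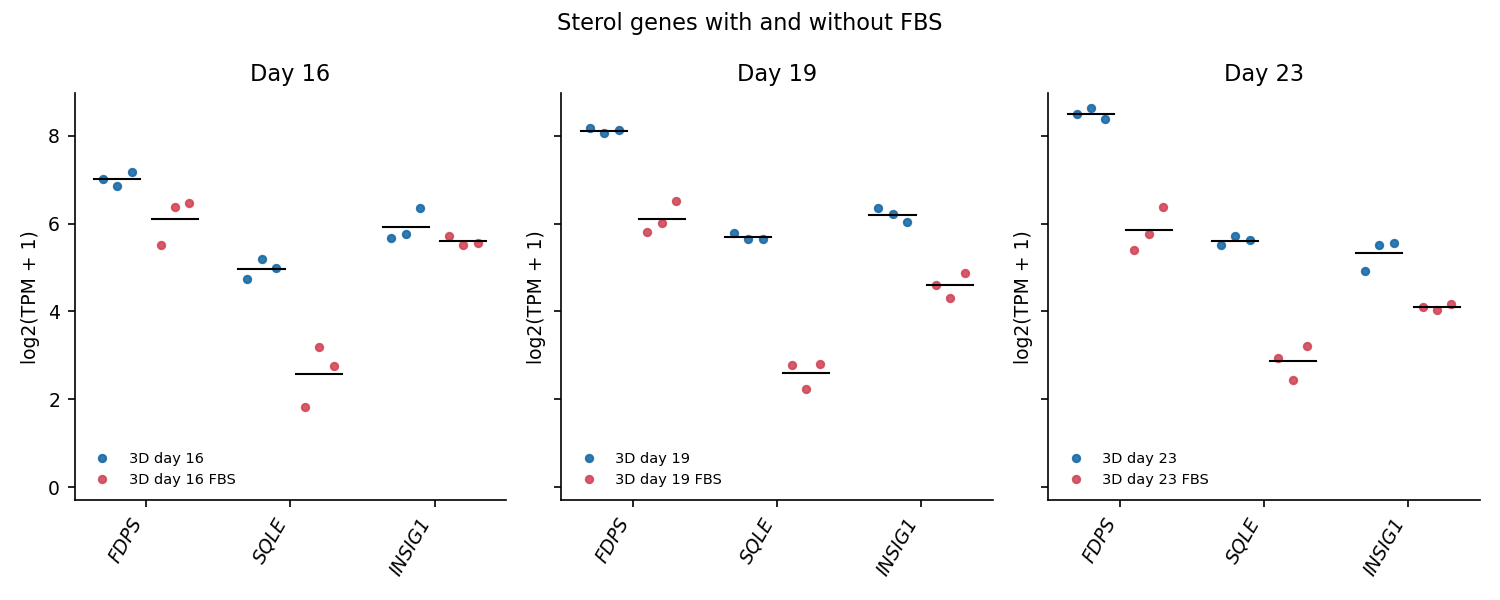
Values of 3 sterol genes at days 16, 19 and 23 of 3D culture without and with FBS in the label, 3 libraries per group, on a log2(TPM + 1) axis, where points are libraries and lines are group means. FDPS and SQLE lie lower in every FBS library of every day, and the points of INSIG1 overlap at day 16.

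FBS also moved signalling and macrophage genes. ID3 (ENSG00000117318, chromosome 1, 23557926 to 23559501), a target of BMP and TGF-beta signalling, rose from 7.94 ± 3.09 to 248 ± 92.6 TPM (SD, n = 9 each, log2 change 4.81, adjusted p = 9.51e-14). TGFBI, a matrix protein induced by TGF-beta, rose from 292 ± 124 to 2381 ± 401 TPM (SD, n = 9 each, log2 change 3.15, adjusted p = 3.72e-14). PDK4, a brake on pyruvate oxidation, rose (log2 change 4.73, adjusted p = 1.72e-09). THBS1, a matrix glycoprotein that activates TGF-beta, rose (log2 change 4.12, adjusted p = 1.28e-08). MARCO fell from 568 ± 496 to 23.2 ± 31.8 TPM (SD, n = 9 each, log2 change -5.06, adjusted p = 6.26e-14). CHI3L1, a secreted chitinase-like protein, fell from 797 ± 463 to 44.7 ± 38.6 TPM (SD, n = 9 each, log2 change -4.59, adjusted p = 1.99e-05). FCN1, a lectin of monocytes, fell from 58.1 ± 46.8 to 3.12 ± 2.95 TPM (SD, n = 9 each, log2 change -3.77, adjusted p = 3.89e-08). Resident genes gained. RNASE1 rose from 1444 ± 787 to 8188 ± 679 TPM (SD, n = 9 each, log2 change 2.79, adjusted p = 3.63e-13). F13A1 rose (log2 change 2.60, adjusted p = 9.57e-12). The growth factor IGF1 rose from 48.7 ± 33.6 to 259 ± 137 TPM (SD, n = 9 each, log2 change 2.89, adjusted p = 2.56e-09). Of 20 genes of the tissue-resident list 14 rose, 1 fell and 5 were not called (15 up and 1 down adjusted over the list alone, camera adjusted p = 2.05e-08). MRC1 rose (log2 change 1.47, adjusted p = 3.03e-08). CSF1R, the receptor for the macrophage growth factor, rose from 186 ± 85.4 to 384 ± 77.7 TPM (SD, n = 9 each, log2 change 1.15, adjusted p = 1.94e-07). Inflammatory genes went down. SOD2, a mitochondrial dismutase induced by NF-kB, fell (log2 change -2.77, adjusted p = 1.69e-11), and so did IL1B (log2 change -2.52, adjusted p = 6.06e-11). Of 37 on the list 6 rose, 21 fell and 10 were not called (8 up and 23 down adjusted over the list alone, camera adjusted p = 1.81e-05). IL1B was not called at day 23 (log2 change -0.12, adjusted p = 0.842, interaction adjusted p = 7.17e-07). Singly by day, 17, 13 and 12 genes of the list fell at days 16, 19 and 23, and 4, 7 and 7 rose. Averaged over the days, FBS came with more RNA of most genes of the tissue-resident list and less of most inflammatory genes. C1QB of the tissue-resident list fell at days 16, 19 and 23 (log2 change -1.02, -1.34 and -1.28, adjusted p = 0.00192, 9.63e-05 and 0.000257).

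GINS2, a part of the replicative helicase, fell with FBS from 6.35 ± 2.64 to 1.29 ± 1.52 TPM (SD, n = 9 each, log2 change -1.86, adjusted p = 4.27e-08) on average. GMNN, the inhibitor of replication licensing, fell from 20.4 ± 8.42 to 3.81 ± 2.43 TPM (SD, n = 9 each, log2 change -2.28, adjusted p = 3.56e-07). Of 39 S phase genes, 0 rose, 21 fell and 18 were not called (0 up and 25 down adjusted over the list alone, camera adjusted p = 5.11e-09). Of 52 G2/M genes 0 rose, 15 fell and 37 were not called (0 up and 14 down adjusted over the list alone, camera adjusted p = 6.54e-05, adjusted p = 0.214 with an estimated correlation). Singly by day, 16, 19 and 3 S phase genes fell at days 16, 19 and 23, and 0, 0 and 1 rose. Of the G2/M genes 4, 0 and 0 rose and 2, 19 and 8 fell. TOP2A rose at day 16 (log2 change 2.38, adjusted p = 0.0235, interaction adjusted p = 0.0277), a call lost when 1 of the libraries is left out. MKI67 fell at day 23 (log2 change -1.85, adjusted p = 0.00567, interaction adjusted p = 0.0204). The mitochondrial chaperone HSPD1, a MYC target, fell (log2 change -1.46, adjusted p = 7.7e-08). Of 30 ribosome biogenesis genes 1 rose, 18 fell and 11 were not called (1 up and 21 down adjusted over the list alone, camera adjusted p = 3.18e-07). Neither GINS2, GMNN nor HSPD1 was called at day 23 (log2 change -0.25, adjusted p = 0.668, log2 change -1.05, adjusted p = 0.112 and log2 change -0.39, adjusted p = 0.344).

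The glycolytic enzyme ENO1 fell with FBS (log2 change -2.02, adjusted p = 3.41e-11). Of 20 glycolysis genes 2 rose, 12 fell and 6 were not called (2 up and 13 down adjusted over the list alone, camera adjusted p = 1.68e-07). Singly by day, 12, 11 and 3 of them fell at days 16, 19 and 23 and 0, 0 and 1 rose, with a camera adjusted p = 0.308 at day 23. MYC fell from 17.4 ± 1.47 to 2.38 ± 0.641 TPM (SD, n = 3 each, log2 change -2.46, adjusted p = 1.02e-05) at day 16. At day 19 it fell from 18.2 ± 5.14 to 1.29 ± 1.23 TPM (SD, n = 3 each, log2 change -3.17, adjusted p = 2.73e-07). At day 23 it rose from 6.71 ± 1.16 to 13.9 ± 3.51 TPM (SD, n = 3 each, log2 change 0.94, adjusted p = 0.0459). That call is lost when 1 of the libraries is left out, under median-ratio scaling and with the replicate block. The interaction of FBS with day had for MYC an adjusted p = 5.42e-06. KLF4 rose from 2.68 ± 1.59 to 16.7 ± 1.99 TPM (SD, n = 3 each, log2 change 2.34, adjusted p = 4.76e-05) at day 16. It rose from 1.71 ± 0.434 to 23.2 ± 7.89 TPM (SD, n = 3 each, log2 change 3.12, adjusted p = 9.89e-07) at day 19. It was not called at day 23 (log2 change -0.29, adjusted p = 0.647, interaction adjusted p = 0.000135). KLF2 rose from 5.79 ± 3.88 to 37.3 ± 24.7 TPM (SD, n = 9 each, log2 change 2.24, adjusted p = 1.89e-05) on average. The immediate early gene EGR1, a zinc finger factor of the growth response, rose (log2 change 2.37, adjusted p = 1.55e-09) but was not called at day 16 (log2 change 0.82, adjusted p = 0.0679, interaction adjusted p = 0.00024). Of 20 such genes 11 rose, 1 fell and 8 were not called (12 up and 2 down adjusted over the list alone, camera adjusted p = 6.54e-05, adjusted p = 0.0672 with an estimated correlation). Singly by day, 2, 14 and 5 rose at days 16, 19 and 23 and 2, 0 and 2 fell. SPP1, the matrix protein osteopontin, fell at days 16 and 19 (log2 change -4.56, adjusted p = 6.67e-09 and log2 change -6.18, adjusted p = 8.09e-11). At day 23 its log2 change was -0.66 (interaction adjusted p = 6.86e-07).

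The labels SP6A and SP14 stand for 3D groups whose meaning is not spelled out. Comparisons with day 12 and with each other address how the 2 differ. The labels give these groups no day, so a difference from day 12 may be one of age. Genes above 0 numbered 21879 and 20003 in the SP6A libraries, 18447 and 17082 in SP14 and 16339 to 16904 at day 12. Against day 12, 2290 genes rose and 1446 fell in SP6A, and 2457 rose and 1744 fell in SP14. With 1 library left out the calls went down in both. With median-ratio scaling they were 1621 up and 2116 down in SP6A and 1822 up and 2375 down in SP14. The median change moved from 0.176 to -0.068 and from 0.093 to -0.14. SELENOP rose from 6.56 ± 2.26 TPM (SD, n = 4) to 1255 and 1316 TPM (log2 change 7.46, adjusted p = 1.22e-12) in SP6A. It rose to 1435 and 1531 TPM (log2 change 7.67, adjusted p = 9e-13) in SP14. OSGIN1, a gene of the oxidative stress response, rose from 2.94 ± 0.895 TPM (SD, n = 4) to 488 and 438 TPM (log2 change 6.91, adjusted p = 4.76e-09) in SP14. PLIN2, which coats lipid droplets, rose from 58.1 ± 14.5 TPM (SD, n = 4) to 5445 and 5894 TPM (log2 change 6.61, adjusted p = 1.02e-12). GPNMB, a glycoprotein of lipid-laden macrophages, rose from 1.59 ± 0.747 TPM (SD, n = 4) to 199 and 216 TPM (log2 change 6.37, adjusted p = 1.24e-06) in SP14. The formyl peptide receptor FPR3 rose from 0.323 ± 0.179 TPM (SD, n = 4) to 104 and 101 TPM (log2 change 6.30, adjusted p = 2.31e-09) in SP14. CSF1R rose from 149 ± 14.2 TPM (SD, n = 4) to 1105 and 1153 TPM (log2 change 2.92, adjusted p = 2.07e-09) in SP6A. In SP14 it rose to 1358 and 1299 TPM (log2 change 3.16, adjusted p = 5.56e-10). CD68, a lysosomal glycoprotein of macrophages, rose from 241 ± 26.2 TPM (SD, n = 4) to 1784 and 1809 TPM (log2 change 2.90, adjusted p = 2.86e-07) in SP14. PLAC8 and FCN1 fell in both groups, in SP14 with log2 change -6.41 and -5.76, adjusted p = 3.87e-07 and 4.51e-07. MYC fell from 25.98 ± 1.77 TPM (SD, n = 4) to 6.22 and 7.99 TPM (log2 change -1.74, adjusted p = 0.000326) in SP6A. It was not called in SP14 (log2 change -0.24, adjusted p = 0.642). KLF2 and KLF4 fell in SP14 (log2 change -2.47, adjusted p = 0.00323 and log2 change -2.69, adjusted p = 4.55e-06).

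The groups of genes below are those of SP6A and SP14 against the same day 12 libraries. Of 37 inflammatory genes, 24 rose, 3 fell and 10 were not called (25 up and 4 down adjusted over the list alone, camera adjusted p = 1.42e-07) in SP6A. In SP14, 25 rose, 4 fell and 8 were not called (26 up and 4 down adjusted over the list alone, camera adjusted p = 1.99e-10). CCL3 rose from 2136 ± 151 TPM (SD, n = 4) to 24036 and 25173 TPM (log2 change 3.53, adjusted p = 3e-11) in SP14. CXCL1, a neutrophil attractant, rose from 234 ± 13.5 TPM (SD, n = 4) to 2986 and 3740.5 TPM (log2 change 3.83, adjusted p = 2.13e-10). Of 32 lysosome genes, 24 rose, 0 fell and 8 were not called (25 up and 0 down adjusted over the list alone, camera adjusted p = 6.61e-13) in SP6A. In SP14, 24 rose, 0 fell and 8 were not called (26 up and 0 down adjusted over the list alone, camera adjusted p = 2.5e-13). PSAP rose from 465 ± 17.5 TPM (SD, n = 4) to 4569.9 and 4675 TPM (log2 change 3.31, adjusted p = 1.53e-11) there. Of 20 tissue-resident genes, 17 rose, 1 fell and 2 were not called (17 up and 1 down adjusted over the list alone, camera adjusted p = 3.8e-13) in SP6A. In SP14, 17 rose, 1 fell and 2 were not called (17 up and 1 down adjusted over the list alone, camera adjusted p = 1.36e-12). Of 24 cholesterol biosynthesis genes, 0 rose, 18 fell and 6 were not called (0 up and 19 down adjusted over the list alone, camera adjusted p = 1.24e-11) in SP6A. In SP14, 0 rose, 15 fell and 9 were not called (0 up and 15 down adjusted over the list alone, camera adjusted p = 3.03e-08). Of 22 LXR targets and lipid genes 11 rose, 3 fell and 8 were not called (11 up and 3 down adjusted over the list alone, camera adjusted p = 0.0043, adjusted p = 0.088 with an estimated correlation) in SP14. ABCA1 rose from 2.26 ± 0.329 TPM (SD, n = 4) to 57.5 and 64.7 TPM (log2 change 4.26, adjusted p = 9.33e-10) there. Of 39 S phase genes, 0 rose, 13 fell and 26 were not called (0 up and 13 down adjusted over the list alone, camera adjusted p = 8.47e-07) in SP6A. In SP14, 0 rose, 14 fell and 25 were not called (0 up and 14 down adjusted over the list alone, camera adjusted p = 9.71e-06). Directly compared, SP14 and SP6A differed in 4 genes (3 higher and 1 lower in SP14, with 428 genes below 0.05 before adjustment). That count ran from 0 with the compared groups alone to 743 with array weights. F3 (ENSG00000117525, chromosome 1, 94529173 to 94541759), the tissue factor that starts coagulation, was higher in SP14, from 2.53 and 3.12 TPM to 16.5 and 17.8 TPM (log2 change 2.25, adjusted p = 0.0245) between SP6A and SP14. That call is lost when any 1 of the 4 libraries is left out. Of 37 inflammatory genes, 1 rose, 0 fell and 36 were not called (6 up and 1 down adjusted over the list alone, camera adjusted p = 2.13e-11) in SP14 against SP6A. A simulated change of 2 on the log2 scale was recovered in 42% of genes with 2 libraries in each group. The noise there came from all 3D groups, not from these 4 libraries alone.

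The E. coli libraries address how the macrophages respond to bacteria. The labels give them no day and no control of their own. They are set against the mean of the 13 libraries of 3D days 12 to 23 without FBS. Of 13384 genes, 1828 rose and 5748 fell, while array weights gave 940 calls. The test shares the spread of all 3D groups. The 2 E. coli libraries agreed less (correlation of 0.657, against 0.891 to 0.968 in other groups). The p-values of this comparison may thus understate the spread between them, which leaves its calls uncertain. In all, 2824 genes were listed at 0 in both E. coli libraries and 3633 in 1 of them. CXCL3 (ENSG00000163734, chromosome 4, 74036589 to 74038689), a neutrophil attractant, rose from 22.4 ± 17.4 TPM (SD, n = 13) to 3087 and 3250.1 TPM (log2 change 7.55, adjusted p = 5.52e-13). F3 rose from 0.866 ± 1.14 TPM (SD, n = 13) to 185 and 319 TPM (log2 change 7.31, adjusted p = 8.08e-15). IFNB1, the type I interferon of infected cells, went from listed at 0 to 58.6 and 107 TPM (adjusted p = 8.54e-17). CCL20, which draws immature dendritic cells, rose from 31.1 ± 30.7 TPM (SD, n = 13) to 1565 and 1178 TPM (log2 change 6.40, adjusted p = 2.12e-13). ACOD1, which makes itaconate, rose from 0.135 ± 0.152 TPM (SD, n = 13) to 38.4 and 92.4 TPM (log2 change 5.77, adjusted p = 1.43e-14). CCL3 rose from 2078 ± 539 TPM (SD, n = 13) to 31734 and 41321 TPM (log2 change 4.18, adjusted p = 4.43e-14). Of 37 inflammatory genes, 30 rose, 1 fell and 6 were not called (30 up and 1 down adjusted over the list alone, camera adjusted p = 9.25e-30). NR4A3, an orphan nuclear receptor, rose from 2.40 ± 2.23 TPM (SD, n = 13) to 95.3 and 79.2 TPM (log2 change 5.10, adjusted p = 5.71e-13). EGR1 rose from 28.99 ± 28.2 TPM (SD, n = 13) to 279 and 507 TPM (log2 change 4.09, adjusted p = 1.06e-10). Of 20 immediate early genes 18 rose, 2 fell and 0 were not called (18 up and 2 down adjusted over the list alone, camera adjusted p = 2.64e-15). The chaperone BAG3, which responds to unfolded protein, rose (log2 change 2.89, adjusted p = 2.91e-07). Of 11 heat shock genes 8 rose, 0 fell and 3 were not called (8 up and 0 down adjusted over the list alone, camera adjusted p = 2.37e-08). IFIT2, which interferon induces, rose (log2 change 5.76, adjusted p = 1.01e-09). IRF9, which carries the interferon signal to DNA, fell (log2 change -5.20, adjusted p = 1.04e-12). Of 26 interferon response genes 9 rose, 9 fell and 8 were not called (9 up and 12 down adjusted over the list alone, camera adjusted p = 0.14). These libraries held RNA of an acute response, with chemokines, tissue factor and interferon beta. KLF4 rose from 3.76 ± 2.22 TPM (SD, n = 13) to 58.97 and 38.5 TPM (log2 change 3.56, adjusted p = 4.24e-09). MYC rose from 17.8 ± 7.68 TPM (SD, n = 13) to 28.4 and 36.9 TPM (log2 change 1.03, adjusted p = 0.00421), a call lost when 1 of the libraries is left out.

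MARCO went from 405 ± 478 TPM (SD, n = 13) to listed at 0 (adjusted p = 1.7e-14). CCL13, a monocyte attractant, fell from 209 ± 156 TPM (SD, n = 13) to 0 and 0.910 TPM (log2 change -6.91, adjusted p = 7.64e-14). Division genes went down. MKI67 fell from 12.7 ± 6.97 TPM (SD, n = 13) to 0 and 0.940 TPM (log2 change -2.94, adjusted p = 2.73e-06). Of 52 G2/M genes 1 rose, 41 fell and 10 were not called (1 up and 43 down adjusted over the list alone, camera adjusted p = 0.000227, adjusted p = 0.238 with an estimated correlation). Of 39 S phase genes, 1 rose, 29 fell and 9 were not called (2 up and 29 down adjusted over the list alone, camera adjusted p = 0.00196, adjusted p = 0.168 with an estimated correlation). Of 24 cholesterol biosynthesis genes, 2 rose, 17 fell and 5 were not called (2 up and 18 down adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.112 with an estimated correlation). INSIG1, a brake on sterol synthesis, rose from 94.4 ± 59.6 TPM (SD, n = 13) to 562 and 529 TPM (log2 change 2.87, adjusted p = 3.29e-10). Transcripts of the mitochondrial genome took 21.2% of the TPM in the E. coli libraries on average. Of 13 mitochondrially encoded genes 12 rose, 0 fell and 1 was not called (12 up and 0 down adjusted over the list alone, camera adjusted p = 4.92e-13, adjusted p = 0.0916 with an estimated correlation). PRG2 rose from 21.9 ± 46.5 TPM (SD, n = 13) to 86.9 and 783 TPM (log2 change 5.80, adjusted p = 0.000792). Of 7 mast cell, basophil or eosinophil markers 4 rose, 0 fell and 3 were not called (4 up and 0 down adjusted over the list alone, camera adjusted p = 0.0142, adjusted p = 0.405 with an estimated correlation). Of the monocyte and macrophage genes, S100A9 fell from 3099 ± 1656 TPM (SD, n = 13) to 919 and 624 TPM (log2 change -1.73, adjusted p = 6.75e-08). CD14 fell from 1109 ± 216 TPM (SD, n = 13) to 488 and 398 TPM (log2 change -1.32, adjusted p = 1.54e-06). MRC1 rose from 52.3 ± 23.4 TPM (SD, n = 13) to 84.1 and 114 TPM (log2 change 1.10, adjusted p = 0.000183). Genes listed at 0 were frequent in these libraries, so a decrease there may be a gene that was missed.

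**Figure D3:**
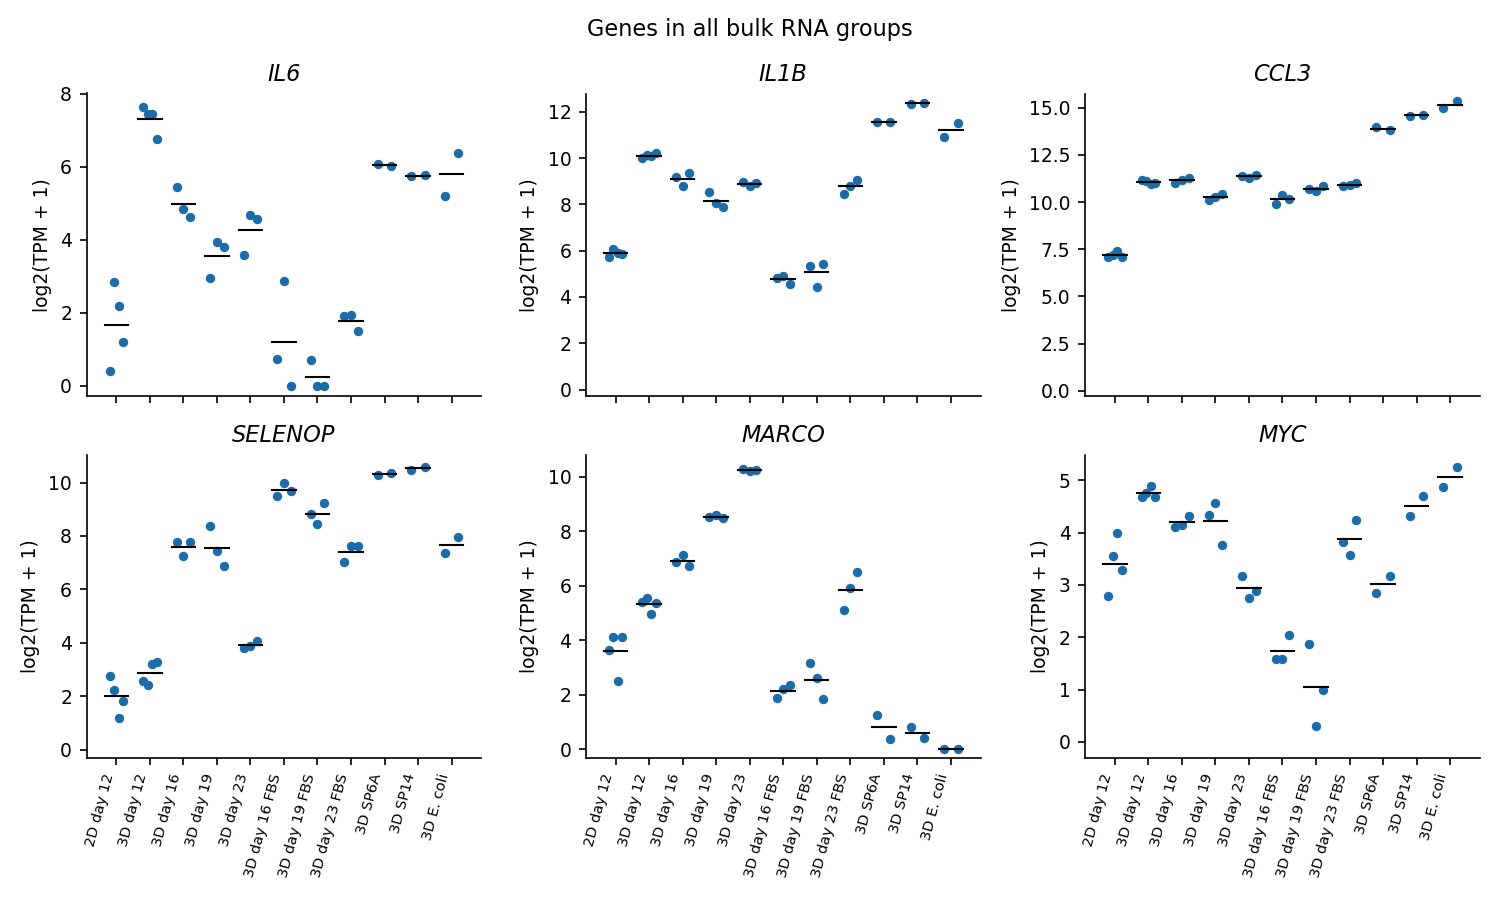
Values of IL6, IL1B, CCL3, SELENOP, MARCO and MYC in all 32 bulk libraries by group on a log2(TPM + 1) axis, where points are libraries and lines are group means. CCL3 is highest in the E. coli libraries, SELENOP in SP14, and MARCO in 3D day 23.

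The single-cell libraries address which cells the 3D culture holds while macrophages appear. Each day is 1 library, so no test between days was made and the intervals below are counting error only. The 25435 cells formed 21 clusters, of which 11 took a name from marker genes by a rule chosen after the clusters were seen. Macrophage-like cells were 0 of 6551 cells at day 7 (a share under 0.0458% could go unseen), 0.319% at day 9 (0.223 to 0.441%) and 28.1% at day 12 (27.1 to 29.1%). They lay in cluster 7 (19.5% of day 12 cells, led by CCL3 and CCL4) and cluster 11 (8.60%, led by RUBCNL and KCNK13). The marker CD14 went from 0.152 CPM (counts of a gene per 1e6 counts) at day 7 and 0.248 at day 9 to 283 CPM at day 12 over all cells. CD163 went from 0.413 to 132 CPM and MRC1 from 3.73 to 311 CPM between days 9 and 12. MARCO was 1395-fold higher at day 12 than at day 9, and IL6 was 257-fold higher, each with its highest level in macrophage-like cells (148 and 127 CPM). The transcription factor SPI1 reached 297 CPM in macrophage-like cells of day 12, where MKI67 was at 215 CPM, MYC at 37.4 CPM and KLF2 at 43.3 CPM. By their cycle genes, 51.9% of these cells (49.7 to 54.04%) were called outside G1 after thinning every cell to the same depth and 47.1% without thinning, with 20 cells left out as too shallow. Over all cells the share outside G1 was 43.5, 43.8 and 30.5% at days 7, 9 and 12 thinned, and 36.3, 38.6 and 26.5% unthinned (278, 729 and 192 cells left out). Such phase calls rest on RNA that may be free of the cell it is counted in and do not show cycling alone.

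**Figure D4:**
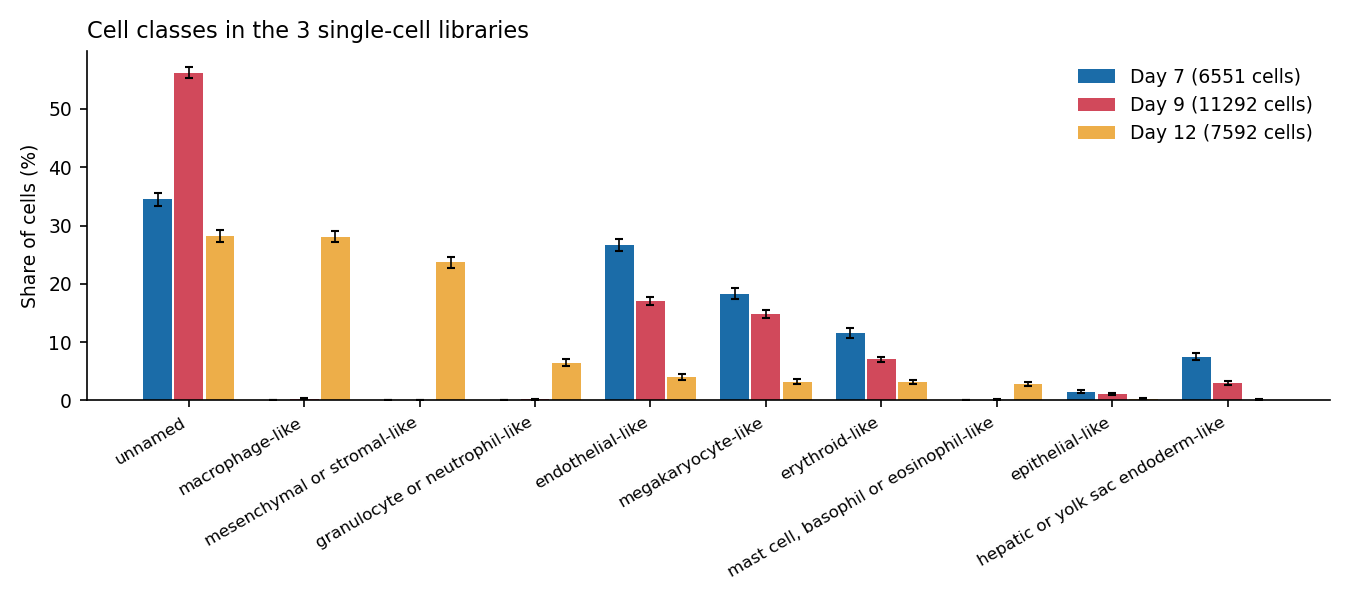
Share of cells (%) in each class at days 7, 9 and 12 of 3D culture, 1 library per day, with bars from 0 and 95% exact binomial intervals that hold counting error only. Macrophage-like clusters hold 0 cells of day 7 and reach 28.1% at day 12, while unnamed clusters hold 56.2% of day 9. The megakaryocyte-like class includes cluster 3, whose name is unsure.

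Other cells filled most of each library. Endothelial-like cells (cluster 0) were 26.7, 17.1 and 4.004% at days 7, 9 and 12, and their gene ESM1, a proteoglycan of sprouting vessels, was 17.6-fold lower at day 12 than at day 9. Hepatic or yolk sac endoderm-like cells (cluster 9) were 7.50, 3.01 and 0.132%, with the apolipoprotein APOA1 15.7-fold lower at day 12 than at day 9. By the naming rule 2 clusters were megakaryocyte-like. Cluster 10, led by PPBP and CLEC1B, was 0.0305, 4.22 and 2.82% of cells. Cluster 3 was 18.3, 10.6 and 0.382%, and its name is unsure, since its 10 leading genes hold 0 megakaryocyte markers but the globin HBD. Erythroid-like cells (cluster 5) were 11.6, 7.04 and 3.14%. PPBP was 160.2-fold and PF4 8.57-fold higher at day 9 than at day 7, both highest in megakaryocyte-like cells. Granulocyte or neutrophil-like cells (cluster 13) were 0.195% at day 9 and 6.45% at day 12, with MPO 1088-fold higher at day 9 than at day 7. The defensin DEFA3, a near-identical copy of DEFA1, was at least 20510-fold higher at day 12 than at day 9, where no count was seen. The alarmin S100A8 had no count at day 7 and was 3567-fold higher at day 9 by the same floor. Mast cell, basophil or eosinophil-like cells (cluster 18) were 0.133% and 2.83% at days 9 and 12, and CLC was 254-fold higher at day 12 than at day 9. Mesenchymal or stromal-like cells (cluster 4) were 0.0153, 0.0797 and 23.7%, and epithelial-like cells (cluster 17) 1.47, 1.09 and 0.303%. Unnamed clusters held 34.5, 56.2 and 28.1%, the largest at day 12 being cluster 6 (22.9%, led by MGP and DCN). The shares of the megakaryocyte-, erythroid-, granulocyte-, mast cell- and stromal-like and unnamed classes depend on the clustering. A cluster mostly of 1 library may be that library. MYC was at 60.1, 27.9 and 34.5 CPM over all cells at days 7, 9 and 12, KLF2 at 31.7, 19.1 and 58.2 CPM and MKI67 at 82.6, 87.8 and 129 CPM. NTS, the neuropeptide neurotensin, was 7.38-fold lower at day 9 than at day 7.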

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

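Of the tests below, those on scaling for the lineage markers, on cluster 10 alone, on genes detected in 3D, on genes with a mean of at least 50 TPM, and on genes taken by the higher of 2 group means were chosen only after the result was seen. The fits without the clone-named genes and on genes above 0 in both E. coli libraries were added once the values had been seen.

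Within the 4 libraries of 3D day 12, PRG2 stood out for a gap between 1 library and the nearest other that took up 0.977 of the range, above Dixon's 95% critical value for 4 libraries. So did EPX, CMTM5 and ARG1 (1 each), CLEC1B (0.961), FBL (0.946), MT-CYB (0.908), HSPA5 (0.904), DEFA3 (0.9), ITGA4 (0.883), HBD and ALDOA (0.872 each) and MXI1 (0.843), and the share of TPM in the 20 highest genes (0.934). In 2D day 12 these were MMP12 (1), PSAP (0.93), STAT2 (0.895), ESAM (0.885), TIPIN (0.86) and KIF2C (0.859). In all, 19 of 274 gene and group values went over the limit, where chance alone marks about 1 in 20 groups.

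The effect of FBS differed between days 16, 19 and 23 in 1728 genes by the interaction test. Of 35 genes of the text tested for it, 20 differed. The adjusted p was 5.42e-06 for MYC, 0.000135 for KLF4, 0.0178 for ID3, 0.000628 for MRC1, 0.000425 for GINS2, 0.00699 for GMNN and 0.0028 for HSPD1. It was 3.29e-05 for RNASE1, 5.42e-06 for F13A1, 0.0373 for IGF1, 7.17e-07 for IL1B, 0.00044 for TGFBI, 6.86e-07 for SPP1, 0.0098 for FDPS, 0.000305 for ENO1, 0.00024 for EGR1, 0.0459 for IL32, 0.000811 for CHAC1, 0.0277 for TOP2A and 0.0204 for MKI67.

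Called markers of megakaryocytes and granulocytes were lower in 3D than in 2D at day 12, with list calls lost at an estimated correlation (adjusted p = 0.0615 and 0.0586), and the list of mast cells, basophils or eosinophils was not called (adjusted p = 0.279). After median-ratio scaling the median change of all measured members of the 3 lists was -2.655, so the scaling of TPM leaves the decrease in place. The explanation written before was that fewer such cells were among those sequenced in 3D. Genes outside the lists that are at least 10 times higher in the matching single-cell clusters than in macrophage-like cells had medians of -1.344 (111 genes, megakaryocyte), -1.524 (47, granulocyte) and -1.11 (38, mast cell, basophil or eosinophil), against -0.212 for all genes. With cluster 10 alone for megakaryocytes, as the name of cluster 3 is unsure, the median was -1.277 (184 genes). These values are consistent with fewer such cells in 3D, yet lower RNA of the same genes in each cell would give them as well, and no 2D single-cell library was used here to separate the 2.

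More genes were called lower than higher in 3D against 2D at day 12. With the 3 clone-named genes removed and TPM closed again, 58.99% of calls were lower, against 65.52% with them kept. That is above the 55% set for their share as the cause, in a fit added once the values had been seen. By that limit these genes alone do not account for the balance, and a part of it went with them. The 3D libraries had a median of 16617.5 genes above 0, and the lowest 2D library had 15846. By genes at 1 TPM or more, every 3D library (11949 to 12272) lay below every 2D library (12693 to 12933), so whether fewer detected genes account for the balance stays open. Median-ratio scaling brought the calls to 2376 up and 2553 down. No biological explanation was tested.

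In the E. coli libraries more genes were called lower than higher. Among genes above 0 in both, 55.92% of calls were lower, but that filter removes 62.11% of lower and 6.729% of higher calls, so that test decides nothing. A second test was added for this reason once the first had been seen. Among the 1900 genes with a mean of at least 50 TPM, 73.32% of calls were lower (937 of 1278), and 69.91% with the 161 genes at 0 in either library left out. That mean is taken mostly over libraries without E. coli, so it keeps genes high there and leaves out induced ones. With genes taken at 50 TPM in the higher of the 2 group means, 59.69% of calls were lower (1072 of 1796). The second test decides nothing either, and missed genes as the reason for the balance stay open.

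Other splits of the same libraries into groups of the real sizes were fitted as well. The real split alone had as many calls (1 of 35) for 3D against 2D (4959, at most 2 elsewhere), day 16 (2219, 551), day 19 (1575, 370) and day 23 (3427, 1306). For FBS on average it was 1 of 100 (4589, 3157). At single days it was 1 of 10 for FBS (2417, 3348 and 1838 calls, with at most 0, 6 and 3 elsewhere), too few splits to tell. For the interaction of FBS with day, 3 of 100 splits had as many calls (1728, up to 3420 elsewhere), and the splits there turn the main effect of FBS into an interaction.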

How the results depend on the processing

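Fits without the E. coli libraries, without the clone-named genes and on genes above 0 in both E. coli libraries were added after the results were seen. Median-ratio scaling, a pseudocount of 0.1 and removal of the clone-named genes left all 13 counts of calls within 1.5 times of the values in the report. The settings that moved a count follow, and the cause was not tested unless stated. A required log2 change of 1 gave 3144 calls for 3D against 2D and 2150 for FBS on average, because it asks for a larger change. Array weights gave 4444 at day 16, 4016 at day 19, 2842 for FBS at day 23, 2913 for the interaction of FBS with day, 743 for SP14 against SP6A, 7423 for SP6A, 7445 for SP14 and 940 for E. coli. Without the E. coli libraries in the fit the calls were 3435 at day 16, 2567 at day 19, 3672 and 2973 for FBS at days 16 and 23, and 3181 for the interaction. Fits on the compared groups alone gave 3762 at day 16, 5974 for SP6A, 6346 for SP14 and 0 for SP14 against SP6A. That last comparison had 22 calls with a pseudocount of 5, 544 with no filter, 2 with a filter at 5 TPM and 7 with trend and robust moderation. With no filter SP6A had 6468 calls. Genes above 0 in both E. coli libraries gave 3968 calls, from fewer genes tested.

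With each library left out in turn, calls ranged from 4012 to 4580 for 3D against 2D, 1500 to 1899 at day 16, 1116 to 1366 at day 19, 2616 to 3031 at day 23, 4230 to 4473 for FBS on average, 1510 to 1963, 2347 to 2928 and 1299 to 1410 for FBS at days 16, 19 and 23, and 1291 to 1803 for the interaction. They ranged from 2003 to 3438 for SP6A, 2568 to 3920 for SP14, 4 to 8 for SP14 against SP6A and 7426 to 7900 for E. coli, where a lone library is assumed to vary like the other groups. Of calls among 11974 named-gene results, 2 reversed, both in E. coli. KLF2 went from -2.616 to 0.009 around -1.304 and CLEC10A from -0.404 to 3.327 around 1.462. Another 324 lost their call and 8 gained one. In the text these are MKI67 (adjusted p up to 0.0611), S100A9 (up to 0.0769) and KLF2 (0.0562) in 3D, CD163 at day 19 (up to 0.11) and MYC with FBS at day 23 (up to 0.187). Others are TOP2A and KLF2 with FBS at day 16 (up to 0.104 and 0.0904), F3 in SP14, KLF2 in SP6A and MYC in E. coli. Of 1412 gene results, a pseudocount of 0.1 ended 42 calls, one of 5 ended 19 and median-ratio scaling 25. Median-ratio scaling ended the calls of MKI67, S100A9, CD163 at day 19 and MYC with FBS at day 23, and MYC at day 16 was called under it (-0.891, adjusted p = 0.0333). Of 458 list results, the estimated correlation ended 103 calls, fry 14, median-ratio scaling 5 and the replicate block 3. New calls numbered 90 with fry, 10 with that scaling and 9 with the block. No called list was called in the other direction under any of these settings.

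The replicate block was tried because groups share replicate numbers. Deviations of libraries with the same number correlated at -0.119 to 0.035, so the numbers do not pair the libraries, although for FBS at day 16 each of the 3 correlated best with its own number (0.007 to 0.017). With the replicate block 3D against 2D had 4110 calls, FBS on average 4470 and E. coli 7264, and no count moved by more than 1.5 times. It ended 27 of 1412 gene calls, with MKI67, S100A9 and MYC with FBS at day 23 among them.

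Shares of single-cell classes depended on the clustering. Macrophage-like cells at day 12 were 27.5% at resolution 1.0, 30.03% with doublets kept and 28.5% under the stricter filter. Megakaryocyte-like cells at day 7 fell from 18.3 to 0.687% at resolution 1.0, to 1.83% with doublets kept and to 0% under the stricter filter. Erythroid-like cells at day 7 reached 31.2% with doublets kept and 30.9% under the stricter filter, where at day 9 they reached 19.98% and megakaryocyte-like cells fell from 14.9 to 2.46%, while mast cell, basophil or eosinophil-like cells went from 0.133 to 0.201%. At day 12, granulocyte or neutrophil-like cells fell from 6.45 to 4.10% at resolution 1.0. With doublets kept, mesenchymal or stromal-like cells at day 12 were 44.3% and unnamed clusters 4.87%. Without thinning, 36.25, 38.61 and 26.54% of all cells were outside G1 at days 7, 9 and 12. Unequal depth of cells enters those unthinned values by construction.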

Other observations

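Further large changes came from genes with other roles. SLAMF7, a receptor that phagocytes use to take up blood cells, fell with FBS from 43.6 ± 14.1 to 2.02 ± 2.81 TPM (SD, n = 9 each, log2 change -4.27, adjusted p = 2.31e-11) on average over the days. The cytokine IL32 fell (log2 change -3.90, adjusted p = 7.32e-09), and IL4I1, an enzyme that breaks down aromatic amino acids, fell as well (log2 change -3.58, adjusted p = 4.43e-09). LRP5, a co-receptor of WNT signals, rose (log2 change 3.85, adjusted p = 9.57e-12). At day 16 with FBS, the metallothionein MT1G went from listed at 0 to 47.7, 53.6 and 33.4 TPM (adjusted p = 0.00881) and CHAC1, which degrades glutathione, fell (log2 change -4.89, adjusted p = 9.69e-07). CHAC1 was not called at day 23 (log2 change -0.39, adjusted p = 0.693).

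Along the time course, TMEM176B, a membrane protein of myeloid cells, rose from 5.15 ± 1.09 to 132 ± 9.69 TPM (SD, n = 4 and 3, log2 change 4.44, adjusted p = 1.36e-05) at day 16. It was up at days 19 and 23 too (log2 change 3.81, adjusted p = 0.000116 and log2 change 4.70, adjusted p = 4.03e-06). ADAMDEC1, a metalloprotease of tissue macrophages, rose from 0.740 ± 0.444 to 45.1 ± 24.9 TPM (SD, n = 4 and 3, log2 change 4.62, adjusted p = 1.63e-08) at day 23. CES1, a carboxylesterase of monocytes, went from 79.1, 65.4, 58.3 and 57.3 TPM to listed at 0 (adjusted p = 4.1e-10) at day 16. In SP6A the endothelin receptor EDNRB rose from 0.0725 ± 0.145 TPM (SD, n = 4) to 64.04 and 63.1 TPM (log2 change 5.92, adjusted p = 5.11e-10) against day 12. With E. coli, RCAN1, a regulator of calcineurin, rose from 11.7 ± 5.34 TPM (SD, n = 13) to 926 and 929 TPM (log2 change 6.33, adjusted p = 1.04e-12).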
